A study of Drosophila melanogaster with 36 samples.

How the data were processed

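Per the labels, poly-A RNA was read from 36 libraries of Drosophila melanogaster. Heads and muscles were read as single ends of 100 nt and whole flies as paired ends of 150 nt. The labels do not say whether replicates come from separate cultures or animals, so the p-values here measure only the spread between libraries. Whole flies were never compared with heads or muscles.

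The deposited values for whole flies are counts of read pairs per gene, made with featureCounts 2.0.1 on exons summed by gene without a strand setting, on the FlyBase annotation r6.36, per the file headers. For these and for heads and muscles the submitters' processing notes name Trim Galore 0.6.6, STAR 2.7.6a, featureCounts 2.0.1 and DESeq2. The deposited values of heads and muscles are whole-number counts per gene followed by 5 tallies in the form that htseq-count writes. That form does not match the tool the notes name, so the counting tool of these 24 libraries is uncertain, and their genome build, annotation release and strand setting are not given in the sources used here. The tallies were left out. As shares of genes and tallies together, reads without a feature came to 3.78 to 4.35% in heads and 1.22 to 2.79% in muscles, ambiguous reads to 3.52 to 3.89% and 2.49 to 3.78%, and reads not uniquely aligned to 4.99 to 6.92% and 5.39 to 36.6%. Without a known strand setting, overlapping and antisense genes can share or lose reads, and near-identical paralogs can lose them. For whole flies the authors also deposited DESeq2 tables with log2 fold changes, their standard errors and an adjusted p-value per gene for the 3 comparisons. Over genes in both, their log2 fold changes have a Pearson correlation of 0.9999 across genes with those computed here. Of the calls among the 10691 genes tested in both, 249, 137 and 240 genes were called here only and 8, 11 and 18 in the authors' tables only, for mutant against WT, transgene group against mutant and transgene group against WT.

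Gene identifiers were matched to FlyBase symbols for 17358 of 17494 genes (99.2%) in heads and muscles and 17547 of 17612 (99.6%) in whole flies. Coordinates are those of the r6.36 annotation in the whole-fly files. The typical biological coefficient of variation was 0.0859 in heads, 0.21 in muscles and 0.0938 in whole flies.

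Each tissue was fitted by itself with one mean per age or genotype, and a fit of all 24 head and muscle libraries gave the interaction of tissue and age from 3 to 45 d (coefficient of variation 0.155). Genes were kept by filterByExpr with a count of 10 and a total of 15, which left 9035 genes in heads, 8866 in muscles, 9538 in the joint fit and 10723 in whole flies. Libraries were scaled with TMM factors, and genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3. All adjusted p-values for genes are edgeR values adjusted by Benjamini and Hochberg over all genes of a comparison, and the threshold is 0.05. The standard error of a log2 change is its size divided by the square root of F. Lists of genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists with 5 or more tested members, and again with an estimated correlation, with fry beside them. Rose and fell are used of genes past the threshold. The list members past it were also counted with p adjusted over the list alone. Overlaps of calls were compared with the number expected of independent lists and with a one-sided Fisher exact test across genes. Where comparisons share libraries, the shared group was divided between them in 6 ways, and 20 simulations without any effect were run.

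The lists were written from known gene functions. They hold antimicrobial peptides, Bomanins and Toll effectors, peptidoglycan recognition, Turandot and heat shock genes, the respiratory chain, the tricarboxylic acid cycle, glycolysis, the proteasome, detoxification, antioxidant, autophagy, insulin, ecdysone, ribosomal, replication, SAGA and other acetylation genes, clock, cuticle and chemosensory genes, and markers of photoreceptors, neurons, glia, muscle, fat body, gut, hemocytes, yolk, eggshell, germline, testis, accessory gland and male dosage compensation. The genes phm, Gmnn, nos, Bicaudal and rye of these lists had no match and were not analysed here. Named genes are Gcn5 and the 8 genes with the largest rise and the 8 with the largest fall in the main comparisons, or 3 in the others, by log2 change. They had to pass the threshold, to average at least 3 in log2 CPM, to show no overlap between the libraries of both groups in CPM and to have a proper symbol. From each list up to 4 members with the smallest p in the direction most members took were named. Of the genes this rule gives, the text names all 76 of the largest changes in the 6 comparisons described at length, but only 8 of 41 in the other ageing steps and 103 of 529 list members. Which of these to print was decided after their values were seen. The text also gives Gcn5 only in the first 6. mt:lrRNA, sordd2 in the mutant, Mhc and ninaE in single libraries, lncRNA:roX1 in single libraries and Hsp68 in muscles were chosen after their values were seen. The samples, comparisons, lists of alternatives and this rule were fixed before the data were examined. For a gene without counts in a group, a fold is given against a floor of 3 counts over the group, and such floors cover counting error only.

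On simulated counts drawn from the means and library sizes of the real libraries, with 200 changed genes, the test recovered 53.7, 82.1 and 97.0% of changes of 1.5, 2 and 4-fold in heads (8946 genes, 12 false calls). For muscles these shares were 2.99, 35.8 and 93.9% (8808 genes, 4 false calls), for the interaction 0, 37.3 and 83.3% (9459 genes, 2 false calls) and for mutant against WT 47.8, 77.6 and 98.5% (10555 genes, 8 false calls). Alternatives tried were median-of-ratios scaling, scaling by library size only, no filter and a stricter filter on low counts, DESeq2 1.42.0, a robust dispersion, the compared groups alone, the replicate number as a block, and each library left out in turn. After seeing the data 4 more were added: 15 d in place of 3 d, mitochondrial genome genes left out, Gcn5 left out of the SAGA list, and Hsp70Bb left out of the heat shock list. Acetylation of proteins was not analysed here.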

Results

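Poly-A RNA was sequenced from adult Drosophila melanogaster in 36 libraries. Heads and muscles of a wild-type strain were sampled at 3, 15, 30 and 45 d of age, with 3 libraries for each tissue and age. Whole flies of 3 d came in 3 genotypes with 4 libraries each. These were wild type (WT), a gcn5 loss-of-function mutant, and that mutant carrying a tub-GAL4 driver and a UAS-HA-Gcn5 transgene, called the transgene group here. The labels name the last group an overexpression of Gcn5, a lysine acetyltransferase of the SAGA and ATAC complexes, and they do not give the sex of the flies. Counts in genes came to between 3.18 and 4.36 M per head library, 3.00 and 3.68 M per muscle library and 1.62 and 2.82 M per whole-fly library. Levels below are CPM with TMM-scaled library sizes, as mean ± SD over the 3 or 4 libraries of a group, and changes are log2 fold changes ± SE.

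The mitochondrial large ribosomal RNA mt:lrRNA was the gene with the most counts in every library, with 2.66 to 6.96% of the counts in heads, 2.10 to 22.1% in muscles and 7.85 to 9.98% in whole flies. Replicate 3 of muscle at 3 d stood apart, with Spearman correlations across genes of 0.841 and 0.843 to the others. Replicates 1 and 2 had 0.982 and the lowest pair in other groups 0.971. Mhc, the muscle myosin heavy chain, stood at 2087 CPM in replicate 3 of muscle at 3 d and at 9584 and 15010 CPM in the other two. ninaE, the main rhodopsin of the eye, stood at 135 CPM in replicate 2 of that group and at 4.82 and 21.7 CPM in the others. Digestive enzyme genes of the gut held 1.35% of the counts of muscle at 3 d and 1.72% at 45 d, against 0.0583% in heads at 3 d. The dosage compensation RNA lncRNA:roX1, of the male X chromosome, stood between 272 CPM in replicate 3 of muscle at 3 d and 2099 CPM in replicate 3 of heads at 3 d, and yolk protein genes held at most 0.00115% of the counts of a whole-fly library. In replicate 3 of muscle at 45 d, 36.6% of the tallied reads were not uniquely aligned; the next highest muscle library had 11.6%.

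Gcn5 (FBgn0020388, chromosome arm 3L, 12521129 to 12524014 of FlyBase release r6.36) was read in every library. In whole flies its transcript stood at 35.9 ± 7.10 CPM in WT and at 36.8 ± 0.560 CPM in the mutant (log2 fold change 0.029 ± 0.12, adjusted p = 0.917, n = 4 each, edgeR). The mutant libraries therefore hold no lowered Gcn5 transcript, and the counts do not test the mutant genotype. With the transgene the level was 2968 ± 166 CPM, a log2 change of 6.33 ± 0.10 from the mutant, and the counts do not separate reads of the transgene from those of the endogenous gene. In wild-type heads Gcn5 rose from 49.7 ± 0.502 to 76.5 ± 6.35 CPM between 3 and 45 d (log2 0.63 ± 0.083, adjusted p = 2.57e-05, edgeR). In muscles it rose from 31.4 ± 13.7 to 73.97 ± 7.50 CPM (log2 1.23 ± 0.25, adjusted p = 0.00485, edgeR), where the 3 libraries of 3 d read 43.0, 35.0 and 16.3 CPM. The muscle rise did not pass with 15 d in place of 3 d (log2 0.31, adjusted p = 0.785). Nor did it pass with only the compared libraries (0.0861). The first fit held the 3 d spread, and 15 d read 57.7 to 61.3 and 45 d 66.8 to 81.8 CPM. The tissue difference in the Gcn5 rise was 0.66 ± 0.25 (adjusted p = 0.134, edgeR). It passed without replicate 1 of muscle at 3 d (0.0139) and with scaling by library size only (0.0012).

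**Figure D1:**
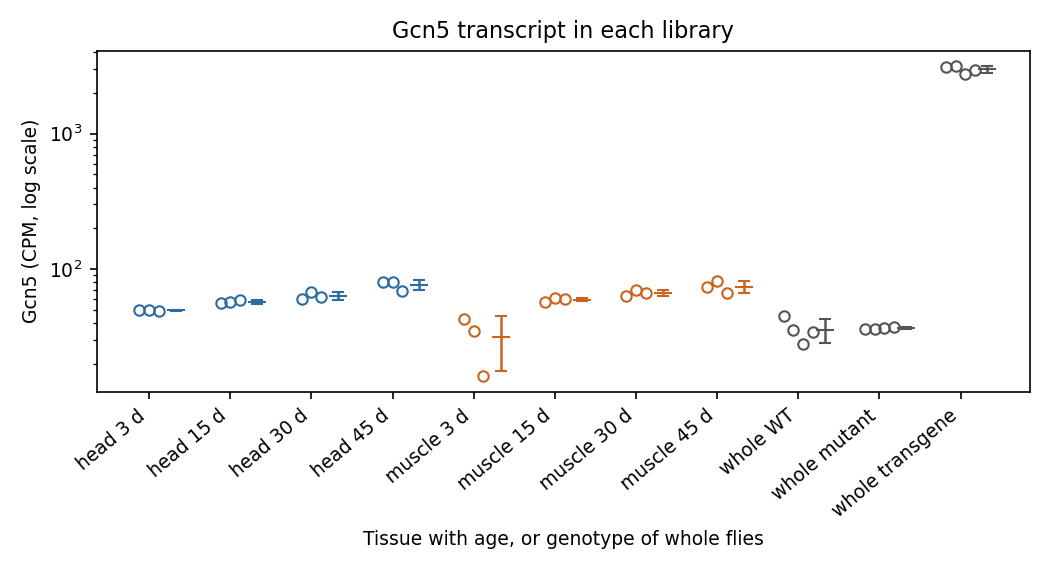
Gcn5 level in each library, in CPM with TMM-scaled library sizes on a log axis, by group. Points are single libraries and bars are means with 1 SD (n = 3 in heads and muscles, n = 4 in whole flies). WT and mutant whole flies lie between 28.3 and 45.5 CPM and the transgene libraries between 2753 and 3123 CPM.

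Ageing heads were compared with 3 d. Most antimicrobial peptide genes rose and most of the respiratory chain, synapse, sarcomere and light sensing fell. No list passed both camera tests. At 15 d 452 genes were higher and 709 lower than at 3 d, of 9035 tested. At 30 d these counts were 1330 and 1502, and at 45 d 1579 and 1648, of which 265 and 196 changed at least 2-fold. Scp1, a calcium-binding protein of the sarcoplasm, fell from 33.2 ± 6.65 to 4.27 ± 0.550 CPM by 15 d (log2 -2.93 ± 0.20), and atk, a leucine-rich repeat protein, rose from 6.66 ± 3.11 to 23.5 ± 4.27 CPM (log2 1.80 ± 0.31). The counts at 15 d rest on single libraries. With no filter on low counts 719 were higher. Without replicate 1 of 3 d they were 252 and 345, without replicate 1 of 15 d 229 and 416, and without replicate 3 of 15 d 289 and 467. With 15 d in place of 3 d, 464 genes were higher and 362 lower at 45 d. With scaling by library size only, which brings the median log2 change of all genes from 0.008 to 0.134, 2418 genes were higher and 1085 lower at 45 d, a share of 69.0% higher in place of 48.9%. The shares at 15 d moved likewise from 38.9 to 63.2%, and those at 30 d from 47.0 to 63.3%.

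Of the antimicrobial peptides, secreted effectors of the humoral immune response, 12 of 14 tested genes rose in heads between 3 and 45 d and none fell, with the same count adjusted over the list alone. AttC (FBgn0041579, chromosome arm 2R, 13393705 to 13394667) rose from 25.4 ± 11.8 to 899.7 ± 536 CPM (log2 5.14 ± 0.62, adjusted p = 9.68e-06), DptA from 5.86 ± 3.22 to 269 ± 159.5 CPM (log2 5.52 ± 0.59) and Mtk from 37.4 ± 12.4 to 495 ± 272 CPM (log2 3.73 ± 0.43). AttA and AttB also rose (log2 5.10 ± 0.71 and 4.99 ± 0.57), and reads of this near-identical pair can be lost or shared. The list held 0.0508% of the counts at 3 d and between 0.187 and 0.556% at 45 d. Of the peptidoglycan recognition genes, receptors and amidases that sense or degrade bacterial cell wall, 10 of 14 rose and none fell (10 adjusted over the list alone), among them PGRP-SD from 14.2 ± 1.34 to 125 ± 30.2 CPM and PGRP-SB1 from 52.4 ± 12.1 to 534 ± 186 CPM. Of the Bomanins and other Toll effectors 13 of 16 rose (14 adjusted over the list alone), such as BomBc3 (log2 1.26 ± 0.12). As sets the 3 lists moved upward against all other genes (camera, adjusted p = 1.1e-10, 3.98e-10 and 3.34e-08), but not in the second camera test (adjusted p = 0.202, 0.202 and 0.247 with an estimated correlation). Of the Turandot genes, a family of stress-induced peptides, 3 of 4 fell and none rose, with the same count adjusted over the list alone.

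Transcripts of the nuclear-encoded respiratory chain fell in heads between 3 and 45 d. In complex I 31 of 32 genes fell, in complexes II to V all 35, and in the tricarboxylic acid cycle 14 of 17, and none rose (31, 35 and 15 adjusted over the list alone). The falls were mostly under 2-fold: ATPsynF, a subunit of the ATP synthase, fell from 282 ± 21.8 to 166 ± 18.6 CPM (log2 -0.77 ± 0.083) and ND-ASHI, a subunit of complex I, from 96.9 ± 3.10 to 64.5 ± 1.19 CPM (log2 -0.59 ± 0.071). mt:lrRNA fell from 68400 ± 5594 to 27380 ± 2546 CPM. Cytosolic ribosomal protein genes rose (62 of 80, median 0.37, with 69 adjusted over the list alone), such as RpS20 (log2 0.57 ± 0.086). Proteasome subunits rose too (27 of 31, 28 adjusted over the list alone). The adjusted p of these 5 lists by camera lay between 2.09e-20 and 8.18e-07, and none passed the second camera test (adjusted p = 0.202 to 0.462). Part of this came after 15 d. When 15 d stood in place of 3 d the 5 lists still passed by camera (adjusted p of at most 0.0244), but few single genes did. In that comparison 1 gene of complex I, 4 of complexes II to V and 1 of the tricarboxylic acid cycle fell, and 1 ribosomal protein gene and 2 proteasome genes rose. The proteasome count was 16 without replicate 1 of 3 d and 17 without replicate 3 of 45 d.

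Neuron and synapse genes fell in heads (20 of 22, none rose, 21 adjusted over the list alone). Syt1, the calcium sensor of synaptic vesicle release, fell from 1612 ± 182 to 855 ± 40.4 CPM (log2 -0.91 ± 0.085), and Gad1, which makes the transmitter GABA, from 751 ± 97.7 to 312 ± 31.3 CPM (log2 -1.26 ± 0.11). Of the photoreceptor genes 18 of 27 fell and 2 rose (19 and 3 adjusted over the list alone). retinin, a protein of the corneal lens, fell from 1696 ± 412 to 396 ± 96.4 CPM, and Calx, a sodium-calcium exchanger, from 471 ± 43.1 to 248 ± 21.2 CPM. Sarcomere genes fell as well (22 of 26, 22 adjusted over the list alone), such as Zasp66, a protein of the Z disc (log2 -1.30 ± 0.088). Of the cuticle proteins 10 of 19 fell, led by Cpr49Ag and Cpr49Ae (log2 -2.80 ± 0.19 and -2.50 ± 0.15), and 4 rose (13 and 4 adjusted over the list alone). The 4 that rose were 2 without replicate 2 of 3 d, 1 without replicate 3 of 3 d and 0 without replicate 3 of 45 d. By camera the adjusted p of these lists were 2.81e-15, 2.43e-09, 8.25e-15 and 6.92e-05 in this order, and none passed the second camera test (adjusted p = 0.202). From 15 to 45 d, 8 neuron, 1 sarcomere and 4 cuticle genes fell, and the sarcomere and cuticle lists no longer passed (adjusted p = 0.338 and 0.0594).

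The inducible heat shock genes fell in heads as a list (8 of 12 fell, 1 rose, the same adjusted over the list alone; adjusted p = 0.0195, and 0.371 with an estimated correlation). None of them fell with 15 d in place of 3 d, and the list did not pass (adjusted p = 0.88). Some detoxification genes rose. Of the cytochrome P450s 19 of 64 rose and 7 fell (21 and 8 adjusted over the list alone). Of the glutathione S-transferases 12 of 30 rose and 1 fell (12 and 2 adjusted over the list alone). Cyp4p2 rose from 39.8 ± 1.46 to 93.2 ± 10.9 CPM and Cyp4p1 from 50.7 ± 1.80 to 99.1 ± 8.04 CPM. Fat body genes rose (7 of 12, with 1 that fell, 8 and 1 adjusted over the list alone), with Lsp1alpha, a larval storage protein, from 0.587 ± 0.604 to 16.1 ± 4.60 CPM. The adjusted p of these 3 lists were 0.00422, 0.0112 and 0.00422 by camera, and they did not pass the second camera test (adjusted p = 0.25, 0.462 and 0.398). From 15 to 45 d, 8 P450s rose and 3 fell. In the same comparison 2 glutathione S-transferases and 3 fat body genes rose, and the P450 and transferase lists no longer passed (adjusted p = 0.214 and 0.707). The P450s that fell numbered 4 without replicate 2 of 3 d and 4 without replicate 1 of 45 d.

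Further lists did not pass in heads at 45 d. Of the ecdysone genes 7 of 16 fell and none rose (7 and 0 adjusted over the list alone), and the list passed without replicate 2 of 3 d (adjusted p = 0.0433) or replicate 1 of 45 d (adjusted p = 0.0252). Of the antioxidant enzymes 6 of 16 rose and 2 fell, of the mitochondrial ribosomal proteins 1 of 71 rose and 6 fell, of the glycolytic genes 2 of 12 rose and 4 fell, of the insulin pathway 3 of 14 rose and 2 fell and of the autophagy genes 1 of 19 rose and 0 fell (7 and 2, 0 and 5, 2 and 4, 3 and 2, then 0 and 0 adjusted over the list alone, in this order). In the SAGA and ATAC complexes 4 of 29 rose and 1 fell, and of the other acetyltransferases and deacetylases 5 of 17 rose and 2 fell (4 and 1, then 5 and 2 adjusted over the list alone, in this order). The latter rise was 2, 3, 2 and 2 genes without replicates 1 or 3 of 3 d and 1 or 2 of 45 d, the rise in SAGA 2 without replicate 2 of 45 d, and the fall in glycolysis 2 without replicate 1 of 45 d. Of the glial genes 4 of 10 rose and 4 fell, of the hemocyte genes 4 of 12 rose and 5 fell and of the female germline genes 4 of 10 rose and 0 fell (4 and 5, 4 and 5, then 4 and 0 adjusted over the list alone, in this order). The glial rise was 2 genes without replicate 3 of 3 d, and the hemocyte fall 3 without replicate 2 or 3 of 3 d. Of the replication genes 2 of 16 rose and 0 fell, of the gut enzymes 3 of 10 rose and 0 fell and of the odorant and gustatory receptors 3 of 26 rose and 1 fell (2 and 0, 3 and 0, then 2 and 0 adjusted over the list alone, in this order). From 15 to 45 d no ecdysone gene or glycolytic gene fell and no antioxidant or other acetyltransferase gene rose, while 1 mitochondrial ribosomal protein gene and no glial gene fell. In that comparison 1 SAGA, 1 glial, 1 hemocyte and 2 germline genes rose. Of the yolk proteins 2 of 3 tested rose, with Yp1 from no count at 3 d to at least 12.7-fold of the floor at 45 d (floor of 3 counts over the group), which did not pass with 15 d in place of 3 d (adjusted p = 0.51), and no eggshell gene was tested. With fry in place of camera the ecdysone (0.00999), antioxidant (0.0188), mitochondrial ribosomal (0.00963), replication (0.0104) and germline (0.0172) lists passed. So did the mitochondrial ribosomal list with no filter on low counts (0.0226) and the germline list with 15 d in place of 3 d (0.047). Further genes with the largest rises in heads at 45 d were mah (log2 6.24 ± 0.53), a putative amino acid transporter, the cecropin gene CecA1 (5.49 ± 0.78) and PGRP-SC2 (5.11 ± 0.56), an amidase that degrades peptidoglycan. The largest falls also held the small heat shock gene Hsp26 (-2.37 ± 0.37), the lysyl oxidase gene Loxl2 (-2.26 ± 0.19) and the cuticle gene Cpr11B (-2.09 ± 0.24). From 15 to 45 d the change of Hsp26 turned upward and did not pass (log2 0.37, adjusted p = 0.723).

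Between 15 and 30 d, 87 head genes rose and 77 fell, among them b, an aspartate decarboxylase of pigment synthesis, from 160.4 ± 13.96 to 95.4 ± 13.7 CPM. Between 30 and 45 d, 42 rose and 10 fell, led by the defensin gene Def, from 3.92 ± 1.62 to 23.4 ± 11.2 CPM (log2 2.53 ± 0.34). These counts moved when single libraries were left out. Without one library in turn the rise from 15 to 30 d held 49, 6 or 41 genes for replicates 1, 2 and 3 of 15 d and 15 or 30 for replicates 2 and 3 of 30 d, and 133 without replicate 1 of 30 d. The fall held 31, 3 or 16 genes for the same replicates of 15 d, and 7 or 9 for replicates 2 and 3 of 30 d. From 30 to 45 d the rise held 23 or 9 genes without replicates 2 or 3 of 30 d, 19 without replicate 1 of 45 d and 73 without replicate 3 of 45 d. The fall held 4, 1, 1, 5 and 65 genes without replicates 2 or 3 of 30 d and 1, 2 or 3 of 45 d. With no filter on low counts 276 rose and 265 fell from 15 to 30 d and 210 and 94 from 30 to 45 d. Fits of the compared groups alone gave 151 and 182 in the first step and 26 risen in the second. DESeq2 called 124 and 19 fallen, and a robust dispersion left 6 fallen in the second. Scaling by library size only gave 63.7% of the calls between 15 and 30 d as higher, in place of 53.0%.

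Muscles at 45 d held far less transcript for contraction, glycolysis and respiration than muscles at 3 d. Of the sarcomere genes 26 of 28 fell and none rose (26 fell and 1 rose adjusted over the list alone). TpnC4 (FBgn0033027, chromosome arm 2R, 5503437 to 5507866), the troponin C of flight muscle, fell from 1388 ± 256 to 27.8 ± 7.99 CPM (log2 -5.64 ± 0.30, adjusted p = 1.5e-07). fln, flightin of the thick filament, fell from 171 ± 27.6 to 7.13 ± 2.29 CPM (log2 -4.57 ± 0.23), and Mf, myofilin, from 14550 ± 3587 to 1000 ± 41.9 CPM (log2 -3.86 ± 0.19). Scp1 fell from 6773 ± 719.9 to 175 ± 21.5 CPM. Of the glycolytic genes 11 of 12 fell and 1 rose, the same adjusted over the list alone. Gapdh1 fell from 10050 ± 589.9 to 559 ± 19.2 CPM (log2 -4.17 ± 0.14) and Pglym78, a phosphoglycerate mutase, from 1695 ± 160.5 to 209.7 ± 5.41 CPM (log2 -3.02 ± 0.15). In the tricarboxylic acid cycle 16 of 17 fell, in complex I 32 of 33 and in complexes II to V 34 of 35 (16, 33 and 35 adjusted over the list alone). Mpcp1, a mitochondrial phosphate carrier, fell from 5153 ± 582 to 263 ± 9.71 CPM, ATPsynC from 9641 ± 721 to 1003 ± 55.8 CPM and mt:lrRNA from 267100 ± 94750 to 19830 ± 2124 CPM. Of these ATPsynC was not called with 15 d in place of 3 d (adjusted p = 0.251).

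The 5 muscle lists moved down against all other genes by camera (adjusted p = 7.62e-38 for the sarcomere, 1.17e-33 for glycolysis, 2.1e-30 for the tricarboxylic acid cycle, 1.85e-31 for complex I and 2.98e-56 for complexes II to V). With an estimated correlation the sarcomere (0.0294), glycolysis and tricarboxylic acid cycle (each 0.000535) and complexes II to V (0.0387) still passed, while complex I did not (adjusted p = 0.147 with an estimated correlation). Together 115 of their 121 tested genes fell, with a median of -2.12, and 117 fell without replicate 3 of 3 d. The fall came early, with 107 genes down at 15 d against 3 d and a median of -1.87. From 15 to 45 d, 11 of the 121 fell, with a median of -0.33. These were 4 of the sarcomere, 4 of glycolysis, 3 of the tricarboxylic acid cycle, 0 of complex I and 1 of complexes II to V, where 1 gene is in 2 of the lists. With scaling by library size only, 100 fell and 3 rose, with a median of -1.25. As shares of all counts, sarcomere genes went from 5.58 ± 2.18% at 3 d to 2.34 ± 0.0757% at 45 d. Those of complexes II to V went from 5.9 ± 0.828% to 2.07 ± 0.1%, and those of fat body genes went from 0.443 ± 0.198% to 1.27 ± 0.104%.

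**Figure D2:**
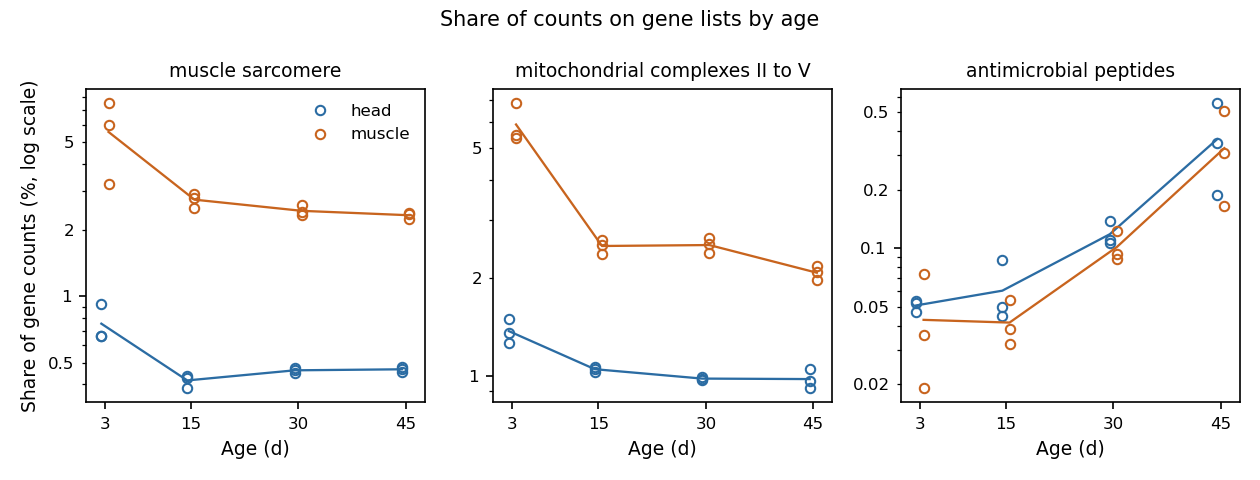
Share of all gene counts held by 3 gene lists in each head and muscle library (% of counts, log axis) against age (d). Points are single libraries and lines join the means of 3 libraries per age. In muscles the sarcomere genes hold 3.23 to 7.53% at 3 d and 2.25 to 2.39% at 45 d, and the antimicrobial peptides reach 0.164 to 0.507% at 45 d.

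Of 3 immune lists 2 passed upward in muscles between 3 and 45 d. Of the antimicrobial peptides 11 of 15 rose and 1 fell (13 and 2 adjusted over the list alone), with AttC from 30.6 ± 22.7 to 647 ± 362 CPM (log2 4.41 ± 0.72), DptB from 21.9 ± 13.7 to 294 ± 169 CPM (log2 3.76 ± 0.56) and Mtkl from 2.66 ± 1.98 to 29.6 ± 14.3 CPM. Of the peptidoglycan recognition genes 6 of 14 rose, the same adjusted over the list alone, such as PGRP-SD from 20 ± 10.9 to 99.3 ± 17.9 CPM. 12 rose without replicate 3 of 3 d but 2 with 15 d in place of 3 d. Both lists passed by camera (adjusted p = 9.69e-06 and 0.000337) but not the second camera test (adjusted p = 0.533 and 0.533), and the peptide list not with scaling by library size only (adjusted p = 0.177). The third, Bomanins and Toll effectors, did not pass (1 of 16 rose, 0 adjusted over the list alone, adjusted p = 0.108). It passed upward without replicate 3 of 3 d (0.000544), where 13 rose, without replicate 2 of 45 d (0.0336), with no filter on low counts (0.0236) and with 15 d in place of 3 d (5.42e-09). The prophenoloxidase genes PPO1 and PPO2 fell (log2 -1.80 ± 0.25 and -1.85 ± 0.27). RnrL, the large subunit of ribonucleotide reductase, rose from 2.25 ± 0.679 to 18.7 ± 2.04 CPM.

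Other muscle lists moved less surely. Proteasome genes passed upward (8 of 31 rose, 10 adjusted over the list alone, adjusted p = 0.000711, and 0.87 with an estimated correlation), with Rpn2 from 128 ± 18.9 to 256 ± 22.1 CPM. The list did not pass with fry (0.0635). 29 of them rose without replicate 3 of 3 d and 2 with 15 d in place of 3 d. Cuticle proteins passed downward (7 of 17 fell and 1 rose, 7 and 2 adjusted over the list alone, adjusted p = 0.0012, and 0.0797 with an estimated correlation). So did mitochondrial ribosomal proteins (15 of 71 fell and 1 rose, 17 and 1 adjusted over the list alone, adjusted p = 0.00263, and 0.892 with an estimated correlation). The medians of both turned positive with scaling by library size only. None of either list fell with 15 d in place of 3 d, where neither passed (0.503 and 0.956), nor did the latter with fry (0.266). The mitochondrial ribosomal proteins that fell numbered 29, 27, 8, 8 and 7 without replicates 1 or 2 of 3 d and 1, 2 or 3 of 45 d. Their list did not pass without replicate 3 of 3 d (adjusted p = 0.712). The photoreceptor list passed downward (genes that fell 7 of 14, the same adjusted over the list alone, adjusted p = 0.00811, and 0.533 with an estimated correlation). It had 4 fallen genes and adjusted p = 0.0693 without replicate 2 of 3 d, whose high ninaE may mark eye tissue. 11 fell without replicate 3 of 3 d and 1 with 15 d in place of 3 d. Replication and cell cycle genes passed upward (3 of 17 rose and 1 fell, the same adjusted over the list alone, adjusted p = 0.0144, and 0.147 with an estimated correlation), but not without replicate 3 of 3 d (adjusted p = 0.109), with 15 d in place of 3 d (0.192) or with scaling by library size only (0.304).

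Across the genome, 180 muscle genes were higher and 536 lower at 15 d than at 3 d, 465 and 798 at 30 d and 728 and 980 at 45 d, of 8866 tested by edgeR. Nplp3, a neuropeptide-like precursor, was among the largest falls at each age, from 1421 ± 677 to 42.6 ± 6.71 CPM by 15 d and to 12.1 CPM by 45 d. Without replicate 3 of 3 d the counts at 45 d were 1943 and 2023, those at 15 d 1037 and 1368 and those at 30 d 1580 and 1758. Leaving out a replicate of the older group lowered them. At 15 d the higher genes became 56, 70 and 85 without replicates 1, 2 and 3 of 15 d, and the lower ones 347 without replicate 1. At 30 d the higher genes became 245, 253 and 246 without replicates 1, 2 and 3 of 30 d, and the lower ones 530 and 520 without replicates 2 and 3. At 45 d the higher genes became 456 and 453 without replicates 1 and 3 of 45 d. With 15 d in place of 3 d, in a fit that kept the spread of the 3 d libraries, 82 genes were higher and 68 lower at 45 d. With scaling by library size only the median log2 change of all genes became 0.888 at 45 d, 0.736 at 15 d and 0.811 at 30 d, and 94.3% of the calls at 45 d were higher in place of 42.6% (95.5 in place of 25.1% at 15 d and 94.7 in place of 36.8% at 30 d). Between 15 and 30 d, 2 genes rose, the metal-binding metallothioneins MtnD from 2.92 ± 0.322 to 42.2 ± 12.9 CPM and MtnE from 7.22 ± 0.635 to 33.8 ± 3.98 CPM, and 6 fell, with Scp1 from 871 ± 76.7 to 256 ± 16.8 CPM. The genes that fell numbered 3 without replicate 2 of 15 d and 1, 2 and 2 without replicates 1, 2 and 3 of 30 d, and with scaling by library size only 5 rose and 6 fell, a share of 45.5% in place of 25.0%. DESeq2 called 28 higher and 36 lower there. Between 30 and 45 d edgeR called 0 genes in either direction, with 317 genes at an unadjusted p under 0.05, while DESeq2 called 11 higher and 19 lower. Without replicate 3 of 45 d edgeR called 1 higher and 10 lower. In fits of the 6 compared libraries alone the counts against 3 d fell to 7 higher and 184 lower at 15 d, 70 and 326 at 30 d and 148 and 441 at 45 d. In such fits without the muscles of 3 d, 363 genes rose and 367 fell between 15 and 30 d, and 157 rose and 170 fell between 30 and 45 d. Other genes with the largest falls in muscles at 45 d were the larval storage protein gene Lsp1gamma (log2 -7.16 ± 0.68), the neuropeptide-like gene Nplp3 (-6.87 ± 0.37), ninaE (-5.91 ± 1.34) and Zasp67 (-5.67 ± 0.66), a protein of the Z-disc. The largest rises also held the attacin genes AttA (4.48 ± 0.75) and AttB (4.04 ± 0.79) and the maltase gene Mal-A4 (3.65 ± 0.51). With 15 d in place of 3 d Lsp1gamma, ninaE, Zasp67 and Mal-A4 did not pass (adjusted p = 0.965, 0.847, 0.461 and 0.167).

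To ask whether ageing differs between both tissues, the change from 3 to 45 d in muscles was set against that in heads with an interaction term. The fall of energy and sarcomere transcripts was larger in muscles. 11 of 12 glycolytic, 16 of 17 tricarboxylic acid cycle, 24 of 33 complex I, 33 of 35 complexes II to V and 13 of 28 sarcomere genes changed more downward in muscles and none more upward (12, 16, 30, 34 and 19 adjusted over the list alone). TpnC4 differed by -6.83 ± 1.06, and Rgk2, a small GTPase of the RGK family, by 1.87 ± 0.37. Neither passed with 15 d in place of 3 d (adjusted p = 0.115 and 0.661). With an estimated correlation glycolysis (adjusted p = 6.04e-07), the tricarboxylic acid cycle (adjusted p = 5.78e-06) and complexes II to V (adjusted p = 0.00901) passed, and complex I and the sarcomere did not (adjusted p = 0.167 and 0.0751 with an estimated correlation). In all, 193 genes changed more upward in muscles and 455 more downward, of 9538 tested. Those counts were 30 and 216 in fits of the compared groups alone, and 507 and 895 without replicate 3 of muscle at 3 d. The first was 107 with no filter on low counts. It was 308 without replicate 1 of muscle at 3 d, 125 without replicate 2 of heads at 3 d, and 126 and 124 without replicates 1 and 3 of muscle at 45 d. From 15 to 45 d they were 3 and 13. Scaling by library size only brought the median of all genes to 0.731 and the share of calls more upward in muscles from 29.8 to 95.2%. Less secure among the largest differences were the arrestin genes Arr1 (-5.88 ± 1.34) and Arr2 (-6.01 ± 1.37) of the eye, the pigment transporter gene bw (3.02 ± 0.82) and the cuticle gene Cpr66D (2.27 ± 0.65). None of the 4 passed with 15 d in place of 3 d (adjusted p = 1, 0.999, 0.0653 and 0.986) or in fits of the compared groups alone (0.067, 0.0514, 0.0674 and 0.156). Arr2 was lost without replicate 2 of muscle at 3 d (0.0524). The call of bw was lost with DESeq2 (0.106), without replicate 2 of heads at 3 d (0.0505), replicates 1 or 3 of muscle at 3 d (0.103 and 0.0781) or replicate 1 of muscle at 45 d (0.126). Cpr66D was lost without replicate 2 of heads at 3 d (0.332), any replicate of heads at 45 d (0.0767, 0.0836 and 0.0793) or replicate 1 of muscle at 45 d (0.0664).

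Many of the same genes changed with age in both tissues. Of 8400 genes tested in both, 429 were higher in both at 45 d, where 119 are expected of independent lists (one-sided Fisher exact p = 8.97e-175 across genes), and 472 were lower in both, where 166 are expected (one-sided Fisher exact p = 4.94e-135 across genes). 30 genes were higher in heads and lower in muscles, and 6 the reverse. The log2 changes had a Spearman correlation of 0.516 across genes, and genes are not independent replicates. AttC, DptA, DptB and Lsp1alpha rose and Scp1 and Nplp3 fell in both, though neither passed in heads with 15 d in place of 3 d (adjusted p = 0.359 and 0.132).

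The gcn5 mutant was compared with WT to ask which transcripts differ between them in whole flies of 3 d. Most genes of gut digestive enzymes and blood cells fell and most of male accessory gland proteins rose, while 2 lists of detoxification genes moved down with a minority of their genes. Of the digestive enzymes 27 of 41 fell and 4 rose (28 and 5 adjusted over the list alone). Among them alphaTry, a trypsin, fell from 2810 ± 311 to 762 ± 261 CPM (log2 -1.88 ± 0.15), Mal-A8, a maltase, from 117 ± 12.2 to 25.6 ± 9.93 CPM (log2 -2.17 ± 0.19) and the protease Jon99Fii, one of a family of close paralogs, from 252 ± 56.3 to 20.9 ± 8.02 CPM (log2 -3.62 ± 0.17). The list held 1.25 ± 0.118% of the counts in WT and 0.549 ± 0.143% in the mutant. Of the accessory gland genes, which encode seminal fluid proteins, 13 of 19 rose and 1 fell (14 and 1 adjusted over the list alone), such as Acp36DE from 1478 ± 49.01 to 3431 ± 324 CPM (log2 1.22 ± 0.069) and Acp62F from 111 ± 6.98 to 248 ± 17.9 CPM. Of the hemocyte genes 8 of 11 fell, the same adjusted over the list alone, such as Hml, hemolectin, from 71.9 ± 8.22 to 36.2 ± 8.90 CPM. Of the cytochrome P450s 20 of 62 fell and 5 rose (26 and 6 adjusted over the list alone), with Cyp28d1 from 207 ± 22.02 to 46.8 ± 6.17 CPM, while the share of counts on this list was 1.66% in WT and 1.7% in the mutant. Of the glutathione S-transferases 7 of 26 fell (7 fell and 1 rose adjusted over the list alone), with GstE5 (log2 -1.77 ± 0.31). By camera the adjusted p of these 5 lists were 7.53e-19, 1.14e-17, 3.29e-05, 4.33e-05 and 0.0148. None passed with an estimated correlation (adjusted p = 0.113 for 4 of them and 0.19 for the hemocyte list with an estimated correlation).

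Some energy gene lists passed downward in the mutant and the proteasome upward. In complexes II to V 12 of 35 genes fell, in the tricarboxylic acid cycle 6 of 18 and in glycolysis 7 of 12, and none rose (18, 7 and 8 adjusted over the list alone). ATPsynC fell from 2093 ± 162 to 1568 ± 182 CPM and Gapdh1 from 1522 ± 108 to 956 ± 189 CPM. Those of complexes II to V numbered 6 without replicate 2 of WT and 7 and 6 without replicates 1 and 3 of the mutant. Of the proteasome subunits 7 of 31 rose (12 adjusted over the list alone), with Prosbeta6 (log2 0.53 ± 0.087). The adjusted p by camera were 4.57e-05, 0.00418, 0.000939 and 7.39e-05. Again none passed the second camera test (adjusted p = 0.689, 0.689, 0.592 and 0.113). The photoreceptor list passed downward (9 of 26 fell, 1 rose, 10 and 1 adjusted over the list alone, adjusted p = 0.0159, and 0.618 with an estimated correlation), with the rhodopsin Rh5 (log2 -1.57 ± 0.20). The testis list passed upward (2 of 23 rose, the same adjusted over the list alone, adjusted p = 0.0309, and 0.689 with an estimated correlation), with topi (log2 0.69 ± 0.17). With fry complexes II to V (0.0695) and the testis list (0.0947) did not pass. Neither the photoreceptor nor the testis list passed without replicate 2 of WT (adjusted p = 0.0759 and 0.331) or without replicate 4 of the mutant (each 0.0731).

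Single genes changed more. mthl8 (FBgn0052475, chromosome arm 3L, 22428 to 26308), a receptor of the Methuselah family, had no count in the 4 mutant libraries and 29.5 ± 5.39 CPM in WT, at least 80-fold lower against a floor of 3 counts over the group. Arc1 (FBgn0033926, chromosome arm 2R, 14357927 to 14360297), a capsid-forming protein related to retrotransposon Gag, rose from 148 ± 16.3 to 1458 ± 520.4 CPM (log2 3.30 ± 0.17, adjusted p = 1.37e-15). phr, a DNA photolyase, rose from 2.14 ± 1.28 to 27.5 ± 2.91 CPM, Blm, a RecQ helicase, from 13.5 ± 2.36 to 47.5 ± 4.71 CPM, and Lsp1beta, a larval storage protein, fell from 80.5 ± 28.7 to 6.44 ± 0.776 CPM. LysD rose (log2 7.21 ± 0.33), and its close paralogs among the lysozymes can share reads. Cp15, an eggshell gene, had no count in WT and 3.44 ± 1.40 CPM in the mutant, at least 10.4-fold higher against the same floor. Further falls among the largest were those of Srg3 (log2 -6.69 ± 0.45) and CecA1 (-3.73 ± 0.36), both of the immune response, the chitin deacetylase gene Cda9 (-5.52 ± 0.42), the glucocerebrosidase gene Gba1a (-3.34 ± 0.39) and the cold-induced gene Fst (-3.22 ± 0.30). Further rises were those of Hsp70Bb, with 1 read over the 4 WT libraries and 1.31 ± 0.892 CPM in the mutant, Cyp4p2 (log2 3.09 ± 0.32), the nucleotidase gene NT5E-2 (2.61 ± 0.18) and the serpin gene Spn77Bb (2.05 ± 0.11). The call of Hsp70Bb was lost without replicate 4 of the mutant (adjusted p = 0.132). In all, 683 genes were higher and 946 lower in the mutant, of 10723 tested by edgeR, and 172 and 328 of them changed at least 2-fold. The tables deposited by the authors call 608 higher and 802 lower, and 1352 genes are called in both with no sign in conflict. Scaling by library size only gave 52.8% of the calls as higher in place of 41.9%.

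The transgene group was compared with the mutant. Besides Gcn5, the eye colour transporter gene w rose from 3.61 ± 1.71 to 65.8 ± 7.54 CPM (log2 4.23 ± 0.22) and the heat shock gene Hsp70Bb from 1.31 ± 0.892 to 96.8 ± 5.32 CPM (log2 6.11 ± 0.24). mthl8 stood at 11.1 ± 4.08 CPM, at least 30.1-fold over the mutant by the same floor. Cyp28a5 rose from 4.09 ± 2.16 to 24.3 ± 4.44 CPM, the maltase gene Mal-A6 from 102 ± 62.2 to 374 ± 92.04 CPM and Amyrel, an amylase relative, from 1.29 ± 1.85 to 15.6 ± 5.55 CPM, while Arc1 fell from 1458 ± 520.4 to 504 ± 50.1 CPM and LysD (log2 -2.64 ± 0.18). CecA1 (log2 3.27 ± 0.37) and Srg2 (3.36 ± 0.52) were among the largest rises. Obp83a (-3.12 ± 0.74), the phosphatase genes Alp10 (-2.19 ± 0.39) and Alp9 (-2.02 ± 0.48), the protease gene Jon65Aii (-1.83 ± 0.19), Cyp4p2 (-1.61 ± 0.26) and Lsp1gamma (-1.60 ± 0.30) were among the largest falls. Obp83a did not pass with DESeq2 (adjusted p = 0.228) or a robust dispersion (0.185), nor Alp9 with the latter (0.119) or without replicate 2 of the mutant (0.0788). In all 565 genes rose and 441 fell by edgeR, and the authors' deposited table calls 506 and 375, of which 849 are called in both.

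Proteasome subunits fell with the transgene (18 of 31, none rose, 24 adjusted over the list alone), such as Rpt4 (log2 -0.77 ± 0.12). Their list passed by camera (adjusted p = 4.22e-15) and with an estimated correlation (adjusted p = 0.0126). Accessory gland genes fell (13 of 19, 16 adjusted over the list alone), with Acp36DE from 3431 ± 324 to 2171 ± 133 CPM. The photoreceptor list passed upward (genes that rose 11 of 26, with 12 risen and 1 fallen adjusted over the list alone), with chp, chaoptin of the photoreceptor membrane (log2 0.72 ± 0.11). Of the cytochrome P450s 16 of 62 rose and 5 fell (19 and 5 adjusted over the list alone), the latter 3 without replicate 3 of the transgene group. Of the cytosolic ribosomal proteins 17 of 85 rose (23 adjusted over the list alone), such as RpS24 (log2 0.37 ± 0.07), and 11, 9, 11 and 11 without replicates 1, 2, 3 and 4 of the transgene group. The neuron list passed downward (genes that fell 5 of 22, the same adjusted over the list alone), such as brp, a protein of the presynaptic active zone (log2 -0.37 ± 0.086). The adjusted p of the last 5 lists were 1.07e-17, 1.76e-05, 0.00102, 2.06e-08 and 0.000834. They did not pass the second camera test (adjusted p = 0.142, 0.238, 0.177, 0.428 and 0.428 with an estimated correlation).

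Energy genes moved up with the transgene as lists, among them complex I, which had not passed in the mutant (adjusted p = 0.0708, though 0.0405, 0.00556 and 0.00967 without replicate 4 of WT and 2 and 4 of the mutant, and 0.012 with no filter on low counts). Complexes II to V did not pass with fry (0.0706). The adjusted p by camera were 1.98e-05 for complex I, 2.19e-06 for complexes II to V, 0.000521 for the tricarboxylic acid cycle and 0.00102 for glycolysis (adjusted p = 0.428, 0.492, 0.428 and 0.428 with an estimated correlation). In this order 5 of 33, 7 of 35, 7 of 18 and 5 of 12 genes rose and none fell (13, 19, 10 and 8 adjusted over the list alone), with Eno, enolase (log2 0.40 ± 0.065) and ND-MLRQ of complex I (log2 0.40 ± 0.097). Without replicates 1, 2 or 3 of the mutant, 3, 17 and 4 genes of complexes II to V rose, and 4 without replicate 1, 2 or 3 of the transgene group. Complex I held 9 and 2 without replicates 2 and 3 of the mutant, and glycolysis 2 without replicate 1 or 3 of the mutant and 3 without replicate 4 of the transgene group. The tricarboxylic acid cycle held 2 without replicate 1 or 3 of the mutant, 3 without replicate 1 of the transgene group and 4 without each of its replicates 2, 3 and 4. The glutathione S-transferase list passed upward (genes that rose 8 of 26, 9 adjusted over the list alone, adjusted p = 0.00747, and 0.137 with an estimated correlation), 5 of them without replicate 4 of the mutant or replicates 1 or 4 of the transgene group. Peptidoglycan recognition genes passed too (2 of 13 rose, 5 adjusted over the list alone, adjusted p = 0.0127, and 0.177 with an estimated correlation), with PGRP-SC2 (log2 1.35 ± 0.22). Digestive enzymes went both ways (16 rose and 14 fell of 41, 20 and 15 adjusted over the list alone, adjusted p = 0.124), with 8 fallen without replicate 2 of the mutant and 9 without replicate 2 of the transgene group. The digestive list passed upward without replicate 2 of the mutant (0.00131) and without replicates 2 or 4 of the transgene group (0.00598 and 0.0483). The SAGA list passed upward although its median was -0.11, and it did not pass with Gcn5 left out of it (adjusted p = 0.336), with no filter on low counts (0.955) or in the second camera test (adjusted p = 0.177).

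The transgene group was also compared with WT, for kept and new changes alike. Digestive enzymes stayed low (21 of 41 fell and 3 rose, 23 and 6 adjusted over the list alone), with Jon65Aiii (log2 -1.41 ± 0.11) and epsilonTry, a trypsin (log2 -2.46 ± 0.18), and the list held 0.624 ± 0.0931% of the counts. The sarcomere list passed downward (genes that fell 11 of 27, 1 rose, 15 and 2 adjusted over the list alone), with the actin gene Act79B from 1430 ± 81.5 to 1058 ± 51.6 CPM. So did the neuron list (9 of 22, 12 adjusted over the list alone), with Rdl, a GABA receptor subunit (log2 -0.41 ± 0.092), and the hemocyte list (4 of 11, 5 adjusted over the list alone), with PPO1 (log2 -1.10 ± 0.25). Testis genes passed upward (7 of 23 rose, 13 adjusted over the list alone), with fzo, a mitofusin of sperm development (log2 0.42 ± 0.094), and 4 without replicate 2 of WT or replicate 3 of the transgene group. In this order the 5 lists had adjusted p = 3.67e-13, 0.00138, 0.00039, 0.00842 and 0.00138 by camera. None passed the second camera test (adjusted p = 0.182, 0.788, 0.57, 0.57 and 0.631). The sarcomere list did not pass with fry (0.0685). sordd2 (FBgn0052581, chromosome arm X, 15796908 to 15799162) had no count in the 4 transgene libraries. By the floor of 3 counts this was at least 106-fold lower than WT and at least 42-fold lower than the mutant. Replicate 2 of the mutant also had none. Hsp70Bb, with 1 read over the 4 WT libraries and 96.8 ± 5.32 CPM with the transgene, and LysD (log2 4.58 ± 0.45) were among the largest rises and the Turandot gene TotM (-4.61 ± 0.55) and Alp10 (-4.35 ± 0.30) among the largest falls, where DESeq2 gave TotM no adjusted p. In all 815 genes were higher and 883 lower by edgeR. The authors' deposited table calls 736 and 761, and 1431 are called in both. Scaling by library size only gave 57.2% of the calls as higher in place of 48.0%.

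Smaller list results against WT depended on single libraries, genes or settings. Proteasome genes passed downward (7 of 31 fell, 1 rose, 10 and 1 adjusted over the list alone, adjusted p = 0.0437, and 0.57 with an estimated correlation), with Rpt3 (log2 -0.51 ± 0.11). That call was lost without replicates 1 or 4 of WT (0.0636 and 0.0658), without replicate 3 of the transgene group (0.146) and with scaling by library size only (0.0789). The count of 7 was 4 without replicate 2 of WT and 4, 3 and 4 without replicates 1, 2 and 3 of the transgene group. Cytosolic ribosomal proteins passed upward (10 of 85 rose and 1 fell, 10 and 1 adjusted over the list alone, adjusted p = 0.00436, and 0.843 with an estimated correlation). With fry they did not pass (0.0569). Their 10 became 2, 18 and 1 without replicates 1, 2 and 4 of WT and 5, 4 and 5 without replicates 1, 2 and 4 of the transgene group. Antimicrobial peptides passed upward (2 of 5 rose, 3 adjusted over the list alone, adjusted p = 0.0186, and 0.182 with an estimated correlation), though not without replicate 1 of WT (adjusted p = 0.0665) or with no filter on low counts (0.125). The inducible heat shock list passed upward (2 of 10 rose, 2 adjusted over the list alone, adjusted p = 0.00138, and 0.127 with an estimated correlation), but not with no filter on low counts (0.235) or with Hsp70Bb left out of it, a test added after seeing the data (0.862), and 1 of them rose without replicate 4 of WT or of the transgene group. The SAGA list passed upward (adjusted p = 0.00735, and 0.182 with an estimated correlation), but not with Gcn5 left out of it (adjusted p = 0.862) or with no filter on low counts (0.55).

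Which of the mutant changes move back in the transgene group? Opposite changes, that is fallen in the mutant and risen with the transgene or the reverse, were called for 268 and 183 genes, 451 in all. Both comparisons share the mutant libraries, so these were also divided between them. The 6 divisions gave 208 to 256 genes where at most 42.4 are expected of independent lists. Of the 268, 187 were not called against WT in the transgene group, which does not show that they were back at its level, 60 stayed on the same side of WT and 21 passed to the other. Of the 183 these numbers were 109, 63 and 11. mthl8, Cyp28d1 and GstE1 fell and rose, and Arc1, Acp36DE and Blm rose and fell. Changes in the same direction against WT in both the mutant and the transgene group were called for 833 genes, 352 higher and 481 lower, and with the WT libraries divided for 474 to 489 where at most 73.2 are expected. Jon99Fii, PPO1 and Act79B fell in both, and Blm, topi and Drsl4 rose in both.

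**Figure D3:**
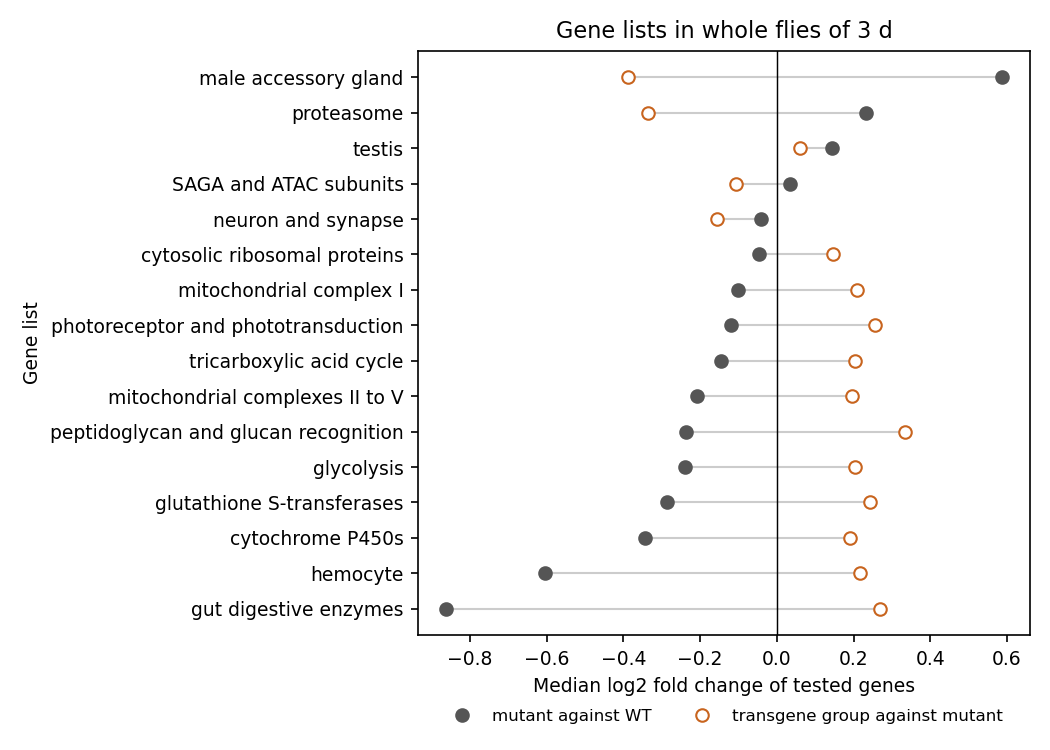
Median log2 fold change of the tested genes of each gene list in whole flies, mutant against WT (filled) and transgene group against mutant (open), with n = 4 libraries per group. Lists shown passed the threshold in at least 1 of both comparisons. Gut digestive enzymes have the lowest median in the mutant (-0.86) and accessory gland genes the highest (0.59).

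Last, the genes that moved in opposite directions in mutant and transgene group were followed in the ageing tissues. The set fallen in the mutant and risen with the transgene moved upward in heads between 3 and 45 d (194 genes tested, camera adjusted p = 0.00423, and adjusted p = 0.334 with an estimated correlation). 75 of it were higher at 45 d where 34.5 are expected (odds ratio 3.02, one-sided Fisher exact p = 2.97e-12 across genes). The set risen in the mutant moved upward too (102 genes tested, adjusted p = 0.00423, and adjusted p = 0.00693 with an estimated correlation). 34 of it were higher where 18.1 are expected. In muscles neither set passed (adjusted p = 0.482 for 217 genes and 0.0515 for 129 genes). The first set held more calls in both directions, with 41 lower at 45 d where 24.3 are expected and 28 higher where 17.29 are expected, and 32 of the other were higher where 10.3 are expected. The set risen in the mutant passed in muscles with median-of-ratios scaling (adjusted p = 0.0358) and with no filter on low counts (0.0168).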

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

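In muscles the change of 8 gene lists from 3 to 45 d differed from that in heads in the interaction test by camera, and the energy lists led. The median interaction log2 change was -1.91 for glycolysis, -1.72 for respiratory complexes II to V, -1.43 for complex I, -1.39 for the tricarboxylic acid cycle and -1.12 for the sarcomere, so these transcripts fell more in muscles. The photoreceptor list lay lower in muscles as well (-2.33, with 7 of 27 genes lower and 2 higher, 15 and 3 adjusted over the list alone), and so did cytosolic ribosomal proteins (-0.55, with 1 of 80 genes, 1 adjusted over the list alone). Neuron and synapse genes lay higher by a median of 0.31, although 0 of 22 passed (0 adjusted over the list alone). The last 3 rest on single libraries. These, complex I and the sarcomere rest on the correlation used (adjusted p = 0.882 each, 0.167 and 0.0751 with an estimated correlation). The photoreceptor call was lost without replicate 3 of heads (0.0709) or muscle (0.053) at 45 d. So it was without replicate 2 of muscle at 3 d (0.706), whose high ninaE may mark eye tissue. The neuron call was lost without replicate 1 of heads at 3 d (0.0794), replicate 3 of heads at 45 d (0.0709), replicate 3 of muscle at 3 d (0.951) or replicate 2 of muscle at 45 d (0.0587), and with scaling by library size only (0.156). The ribosomal protein list turned around without replicate 3 of muscle at 3 d (6.72e-05) and its median turned positive with scaling by library size only. With fry in place of camera the photoreceptor (0.427), ribosomal protein (0.565) and neuron (0.515) lists did not pass, nor the first 2 with 15 d in place of 3 d (0.949 and 0.288). Complex I did not pass with 15 d in place of 3 d (0.593). Named genes had interactions of -6.83 for TpnC4, -5.88 for Arr1, -6.01 for Arr2, 3.02 for bw, 2.27 for Cpr66D and 1.87 for Rgk2. None of the 6 passed with 15 d in place of 3 d, and bw and Cpr66D were also lost without single libraries.

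Among whole flies, single libraries stood apart from the other 3 of their group by the gap to their nearest neighbour. Replicate 2 of WT was high for 6 genes: Eno with 1394 CPM, Gapdh1 with 1684 CPM, ND-MLRQ with 293 CPM, Rdl with 292 CPM, Spn77Bb with 48.3 CPM and mthl8 with 37.5 CPM. In the mutant, replicate 4 was high for TotX with 82.0 CPM, TotM with 99.1 CPM, Srg3 with 1.28 CPM and the eggshell gene Cp15 with 5.55 CPM, and low for PGRP-SC2 with 9.40 CPM. In the transgene group, replicate 1 was low for Act79B with 981.5 CPM and high for Srg2 with 47.6 CPM, replicate 3 was high for LysD with 17.7 CPM and Jon65Aii with 16.58 CPM, and replicate 4 for Srg3 with 4.82 CPM. LysD also stood apart in replicate 3 of WT with 0.914 CPM and Hsp70Bb in replicate 1 of WT with 0.402 CPM, both from at most a few reads. Chance puts about 1 in 20 such groups past the limit used, and 18 of 186 passed it here (9.68%). Groups of 3 libraries were not tested in this way.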

How the results depend on the processing

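Of 164 gene results, each a gene in 1 comparison, 143 kept their side of the threshold in every alternative, as did 97 of 209 list results in those run on lists. The cause of a move was not tested unless given here. Scaling by library size only moved most calls of ageing upward. In heads they became 785 higher and 457 lower at 15 d and 2418 and 1085 at 45 d. In muscles they became 4911 and 234 at 15 d, 5429 and 305 at 30 d and 5827 and 351 at 45 d, with 5 higher from 15 to 30 d. In the interaction they became 4324 and 219, with 14 lists in place of 8. An estimated correlation lowered the number of lists past the threshold in heads from 16 to 0, in muscles from 12 to 4 and in the interaction from 8 to 3. It lowered them in mutant against WT from 11 to 0, in transgene group against mutant from 13 to 1 and in transgene group against WT from 10 to 0. With fry 22 list results came past the threshold and 10 were lost. The set fallen in the mutant no longer passed in heads (0.334). With no filter on low counts 719 head genes were higher at 15 d, with 276 higher and 265 lower from 15 to 30 d and 210 and 94 from 30 to 45 d. It also made 1 muscle gene higher from 30 to 45 d and 107 genes higher in the interaction, and the set risen in the mutant passed in muscles (0.0168), as it did with median-of-ratios scaling (0.0358). DESeq2 called 124 head genes lower from 15 to 30 d and 19 from 30 to 45 d, and in muscles 28 higher and 36 lower from 15 to 30 d and 11 and 19 from 30 to 45 d. A robust dispersion left 6 head genes lower from 30 to 45 d. Fits of the compared groups alone gave in heads 151 higher and 182 lower from 15 to 30 d and 26 higher from 30 to 45 d. In muscles they gave 7 and 184 at 15 d, 70 and 326 at 30 d, 148 and 441 at 45 d, 363 and 367 from 15 to 30 d and 157 and 170 from 30 to 45 d. In the interaction they gave 30 and 216. With 15 d in place of 3 d, an alternative chosen after seeing the data, 464 and 362 head genes, 82 and 68 muscle genes and 3 and 13 genes of the interaction were called. Hsp26 in heads turned upward (log2 0.371, adjusted p = 0.723). Cytosolic ribosomal proteins in muscles moved upward (0.0424). So they did without replicate 3 of 3 d (1.37e-13), but without replicate 1 or 2 of 3 d they passed downward (0.0225 and 0.0387, and up to 0.731 without others). Without that library they turned around in the interaction too (6.72e-05, range 3.77e-10 to 0.0082). Bomanins turned around in transgene group against WT without replicate 3 of WT (0.0213, range to 0.946). With the replicate block 16 head genes were lower from 30 to 45 d in place of 10, the set risen in the mutant passed in muscles (0.0172), Bomanins and Toll effectors passed in muscles (0.0303) and Cpr66D did not pass in the interaction (0.062). The numbers share no known origin: deviations of libraries with the same number had correlations of -0.24 to 0.15 in heads, with 2 of 18 over 0.1, of -0.12 to 0.095 in muscles and of -0.079 to 0.029 in whole flies. Leaving out 1 library in turn gave in heads 229 to 502 genes higher and 345 to 641 lower at 15 d, 6 to 133 and 3 to 109 from 15 to 30 d, and 9 to 73 and 1 to 65 from 30 to 45 d. In muscles it gave 56 to 1037 and 347 to 1368 at 15 d, 245 to 1580 and 520 to 1758 at 30 d, 453 to 1943 and 681 to 2023 at 45 d, 1 to 5 lower from 15 to 30 d, and 0 to 1 and 0 to 10 from 30 to 45 d. In the interaction it gave 124 to 507 and 338 to 895 genes and 6 to 13 lists, while the counts of the whole-fly comparisons stayed within 1.5 times. Leaving out mitochondrial genome genes moved no count or call past these limits, nor did the stricter filter for genes. At 1.62 to 4.36 M counts, genes of a few CPM rest on few reads. In the simulations changes of 1.5-fold were often missed, in muscles more than in heads.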

Other observations

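Some gene groups changed in ways the comparisons above do not describe. In whole flies the clock gene Clk, a transcription factor of the circadian loop, rose in the mutant from 82.8 ± 7.60 to 169.9 ± 4.97 CPM (log2 1.04 ± 0.088) and stayed above WT in the transgene group (log2 0.57 ± 0.088), and of the clock list 3 of 13 rose and 1 fell in the mutant (4 and 1 adjusted over the list alone, adjusted p = 0.315). The labels give no time of day, so a shift in sampling time and a change of the clock cannot be separated. Of the odorant-binding proteins, small carriers of odorants, 7 of 22 fell and 2 rose in the mutant (7 and 3 adjusted over the list alone, adjusted p = 0.315, and 0.0275 with fry). Obp56a fell there from 12.1 ± 2.77 to 2.10 ± 1.49 CPM and rose with the transgene to 29.01 CPM. It also rose with age in heads from 2.63 ± 0.343 to 29.6 ± 2.93 CPM, where 7 of 26 such genes rose and 3 fell (7 and 4 adjusted over the list alone, adjusted p = 0.26), with 4 risen without replicate 1 of 3 d and 3 with 15 d in place of 3 d. The X chromosome RNA lncRNA:roX1 fell with age in heads from 2074 ± 36.5 to 1181 ± 69.4 CPM and lncRNA:roX2 from 64.3 ± 1.05 to 32.01 ± 3.53 CPM, while their dosage compensation list did not pass (of 7 genes 2 fell and 1 rose, 2 and 2 adjusted over the list alone, adjusted p = 0.186, and 0.00112 with fry). All 4 tested Turandot genes fell in the mutant (4 adjusted over the list alone), among them TotX from 156 ± 51.5 to 32.1 ± 33.3 CPM, and 2 of the 4 without replicate 2 of WT or without replicates 1, 2 or 3 of the mutant. The authors' deposited table calls TotX (adjusted p = 0.00104) but not TotA (0.233) or TotC (0.326) and gives none for TotM, and replicate 4 of the mutant held 0.197% of its counts on the list, within the 0.132 to 0.227% of WT. Inducible heat shock genes differed between muscle libraries of one age: Hsp68 stood at 35.7 CPM in replicate 2 and 745.5 CPM in replicate 3 of 45 d.

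The large fall of sarcomere, glycolytic and respiratory transcripts in muscles was weighed against 3 other readings, and the test on the share of flight muscle was chosen only after the result was seen. A single deviating library is argued against, since without replicate 3 of 3 d 96.7% of the 121 genes fell. A difference of the 3 d samples alone stays open: from 15 to 45 d the median of the 5 lists was -0.33 and 11 genes fell, and an effect of maturation in young adults or of how these 3 samples were collected cannot be told apart from ageing in a design with 1 sampling per age. A lower share of flight muscle at 45 d would raise the markers of all other cell types alike, and the neuron list fell instead with TMM scaling, with an upper end of its 95% interval of -0.0926, but rose with scaling by library size only (0.236 to 0.75), so the scaling decides and the reading stays open. Loss of muscle transcripts with age, the biological reading, was not tested apart from these, and 107 of the 121 fell between 3 and 15 d.

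For the rise of w and Hsp70Bb with the transgene all tests were chosen after the result was seen. A heat shock response is argued against, since the other tested inducible heat shock genes had a median log2 change of -0.126 while Hsp70Bb rose by 6.11. Reads shared between Hsp70 copies stay open: the others had 0.0987 reads per 100 on Hsp70Bb, but paralogs can lose them. Transgenic vectors of flies often carry a w marker gene and pieces of an Hsp70 gene, so vector sequence may explain both rises (log2 4.23 for w), but counts per gene do not show which part of a gene was read. A change of these genes by Gcn5 itself, the biological reading, was not tested apart from this.

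The 833 genes changed in the same direction from WT in both the mutant and the transgene group were weighed next, where the test on the shared WT libraries was chosen only after the result was seen. Chance from the WT libraries used in both comparisons is argued against: with these divided, the lowest count was 6.48 times the highest count of independent lists. Variants linked to the gcn5 alleles, carried by both genotypes, may explain a small part, since 10.7% of these genes lie within 5 Mb of Gcn5 and 7.98% of the other tested genes (ratio 1.34, two-sided Fisher exact p = 0.00835 across genes). The 634 outside chromosome arm 3L, 227 on 3R of that chromosome and 4 on the mitochondrial genome, may come from strain background. With 1 WT strain this cannot be told apart from an effect of lost Gcn5 that the transgene does not restore. Loss of Gcn5 function without return by tub-GAL4 is the biological reading and was not tested apart from the background.

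Other planned assignments of the same libraries to groups were tested. The real values were 1629 calls for mutant against WT, 1006 for transgene group against mutant and 1698 for transgene group against WT. The highest other splits gave 0, 6 and 1, so 1 of 35 was as large in each. For independent libraries this excludes chance at an unadjusted 0.05, but not a culture difference. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. In heads the real values were 1161 at 15 d, 2832 at 30 d and 3227 at 45 d against 3 d, 164 from 15 to 30 d and 52 from 30 to 45 d, with highest others of 0, 0, 1, 1 and 1. In muscles they were 716, 1263, 1708, 8 and 0, with highest others of 0, 0, 1, 0 and 0, and in the last all 10 splits gave 0. For the interaction, with 648 calls, 6 of 100 splits were as large, so chance cannot be excluded by this count, and the highest other split gave 1840, which points to a structure of the libraries. Of the 5 others as large, 4 kept muscles of 3 and 45 d apart and so still hold the age difference of muscles, which limits what the count says on chance.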
